A study of Nicotiana tabacum with 12 samples.

How the data were processed

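The data are single-colour (Cy3) oligonucleotide arrays of tobacco leaf and root RNA, read at 0, 20 and 40 min and 1, 2 and 4 h after seedlings were taken out of liquid medium and left to air dry. The 12 deposited samples, each a tissue at a time, hold 3 arrays each, 36 in all, which per the labels are biological replicates of 20 plants each. The authors' values are RMA-normalized expression values per feature, in intensity on a linear scale, deposited as 1 file per array. RMA is background correction, quantile normalization and median polish over the probes of a feature, of which 126506 of 126892 features had 3. Software, version and filters were not stated. The table of 1 value per sample that was deposited beside them, also in intensity, equalled the geometric mean of a sample's arrays for 100% of 126816 features at a tolerance of 1%. Array medians lay between 261.8 and 274.8 in the leaf and between 510.3 and 545.0 in the root, so the tissues appear to have been normalized apart, and levels were not tested between tissues, only changes from 0 min.

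Names come from the annotation column of the files, which gives a UniRef entry for 57285 of the features, and therefore rest on sequence similarity. A further 166 features, such as WRKYnew86, were named by their own identifier on the array. Genome positions were not used here. A UniRef name was used when it was informative, came from a land plant and was not marked as weakly similar. With the features named by identifier, 13461 features had a usable name and 113431 had none. Feature identifiers are given as in the files where a name has several features or is first reported. Where members of a list are counted by name, that name was picked after its values were seen.

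Values were taken to log2 and fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean for each time over the 18 arrays of a tissue. Each time was set against 0 min by limma's test (2-sided), an F test was taken over the 5 contrasts, and the root change minus the leaf change was tested at each time in a fit of all 36 arrays. P values were adjusted by Benjamini and Hochberg over the 126892 features of a contrast, and a feature was called at an adjusted p under 0.05. No filter was applied. The choice of comparisons, tests, gene lists, alternatives and the rule for named genes was made before the data were examined.

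The rule for named genes took, among called features in which every array of the time lay beyond every array of 0 min, 1 feature per name: the 12 largest rises and 12 largest falls in each tissue at 4 h, 6 and 6 at 20 min and 3 and 3 at 40 min, 1 h and 2 h. It also took 3 and 3 for the difference of tissues at 20 min and at 4 h, and from each list the 3 members with the smallest p at 4 h in either tissue. The 22 lists, fixed by name patterns, were ABA synthesis and breakdown, ABA signalling, LEA proteins and dehydrins, compatible solute metabolism, aquaporins, jasmonate synthesis and signalling, nicotine synthesis, ethylene synthesis, WRKY, AP2/ERF, NAC and MYB factors, heat shock proteins and factors, redox enzymes, cell wall loosening, photosynthesis, ribosomal proteins, cell cycle and histones, pathogenesis-related, housekeeping, organelle-encoded and rRNA, and epidermis, vascular and root-hair markers. Of the 236 photosynthesis features 9 are also in the organelle list. The name patterns miss some genes: GmMYB29B2 protein is not in the MYB list and RAP2-like protein is not in the AP2/ERF list. Each list was compared with all other features by camera (limma, 2-sided) with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Calls were also counted with p adjusted over the list alone.

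Overlaps of calls between tissues were set against independent lists by Fisher's exact test. Overlaps within a tissue share the 0 min arrays and were set against independent lists, with the covariance and correlation of changes beside those of groups simulated without change. The fits were tested on simulated data with 200 changed features and independent noise. Changes of 4-fold were recovered for 83.3% to 90.9% of features in the leaf, 92.4% to 95.5% in the root and 57.6% to 66.7% in the difference. Changes of 2-fold were recovered for 2.99% to 7.46% in the leaf, 38.8% to 43.3% in the root and 1.49% to 5.97% in the difference. The root F test recovered 90.9% of 4-fold and 19.4% of 2-fold changes. Each comparison had 1 to 9 false calls. More features were called in every comparison of the data, which eases the adjusted threshold, so these figures do not describe those comparisons. In simulated lists of 60 features the 1 shifted list was called in both tissues and 0 others. Members of these lists were simulated without correlation, so this sets no level for false calls of lists in the data. The median residual SD was 0.35 log2 units in the leaf and 0.27 in the root, and the number of arrays limits the precision.

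The alternatives were quantile normalization and median centring of the arrays, an offset of 16 before log2, array weights, a trend and robust variance, fits of the compared groups alone, stricter thresholds, leaving out the 33.3% of features with the lowest mean, leaving out each array in turn, and an estimated correlation for the lists. Leaving out the arrays that stand apart and a photosynthesis covariate in the root were added after the data had been seen. A slide or scan-date block was not run, since each array is its own slide, the root slots follow time and the leaf names give no date. A replicate block was not run because replicate numbers are not tied to files. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.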

Results

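Transcripts of leaves and roots were measured in 2-week-old seedlings of the tobacco cultivar Burley 21 (Nicotiana tabacum) that had been lifted out of their liquid medium and left to dry in air. Each tissue was taken at 6 times, 0, 20 and 40 min and 1, 2 and 4 h, and the plants harvested at 0 min served as the control. There were no undried plants at the later times. Effects of lifting, handling, loss of the medium and time of day therefore cannot be told apart from drying in any comparison below. Every time and tissue was read on 3 single-colour arrays, which the labels describe as biological replicates of 20 plants each, so 12 groups and 36 arrays entered the comparisons, with 126892 features tested on each. The deposited values had array medians of 261.8 to 274.8 intensity units in the leaf and 510.3 to 545.0 in the root. The lowest correlation of log2 values between replicate arrays of a group, across features that are not independent replicates, was 0.964 in the leaf and 0.976 in the root. The number of arrays, 3 per group, limits the precision of every value. Changes below are log2 changes from 0 min of the same tissue ± standard error (SE), from limma, with n = 3 arrays at each time. The largest named changes are those among the 13461 features with a usable name, with 1 feature per name, and features without such a name could change more. For the genes named by the largest changes, all 3 arrays of the time lay beyond all 3 of 0 min, which chance gives in 10% of features. Adjusted p values of gene lists are from camera (limma), with counts of each list adjusted over the list alone in the order in which its rises and falls were named.

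The leaf series asked how the shoot responded to water loss, and within 20 min the largest named rises included genes known for their fast induction in defence. Avr9/Cf-9 rapidly elicited protein 231 precursor (TC23903), named after the fast response of tobacco carrying a tomato resistance gene to a fungal peptide, rose by 4.28 ± 0.46 (19.5-fold, adjusted p = 4.66e-05), from a mean log2 intensity of 8.69 ± 1.35 to 12.97 ± 0.71 (SD). Avirulence-like protein 1 (EB440199) rose by 3.77 ± 0.52 (adjusted p = 0.000524), Avr9/Cf-9 rapidly elicited protein 20 (TC20908) by 3.55 ± 0.50 (adjusted p = 0.000704) and Avr9/Cf-9 rapidly elicited protein 111B (TC14186) by 3.51 ± 0.44 (adjusted p = 0.0002). Probable phospholipid hydroperoxide glutathione peroxidase (FG645026), an enzyme that reduces oxidised lipids, rose by 3.61 ± 0.31 and GMFP5 (TC35931) by 3.51 ± 0.24. Of the 77 features of AP2/ERF factors, a family of regulators of stress genes, 24 rose and 0 fell, among them 3.04 for Wound-responsive AP2 like factor 1 (TC27213). For AP2/ERF factors the counts adjusted over the list alone were 32 and 0, with adjusted p = 1.12e-25, and adjusted p = 0.00265 with an estimated correlation. WRKY factors, regulators best known from defence, had 24 of 173 features higher and 0 lower. For WRKY factors the counts adjusted over the list alone were 32 and 0, with adjusted p = 5.07e-13, and adjusted p = 0.0142 with an estimated correlation. In the list of abscisic acid (ABA) synthesis and breakdown 3 of 13 features rose and 0 fell, and all 3 carried the name ABA 8'-hydroxylase CYP707A1, the enzyme that breaks the hormone down. For ABA synthesis and breakdown the counts adjusted over the list alone were 5 and 0, with adjusted p = 3.43e-09, and adjusted p = 0.000941 with an estimated correlation. Cell wall loosening had 14 of 140 features higher and 0 lower, 7 of them named Xyloglucan endotransglucosylase-hydrolase XTH9 and 5 XTH3, enzymes that remodel wall xyloglucan. For cell wall loosening the counts adjusted over the list alone were 14 and 1, with adjusted p = 0.0221, and adjusted p = 0.396 with an estimated correlation.

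Few features fell in the leaf at 20 min. Aquaporin 1 (AM825489), a water channel, fell by 1.38 on the log2 scale (SE 0.23, adjusted p = 0.00262), and Oxygen evolving complex 33 kDa photosystem II protein (TC15139) had a change of -1.75 ± 0.36. These were 1 of 4 and 1 of 3 features of their names, and no other of those names was called. Photosystem I subunit XI (TC34815) changed by -1.22 ± 0.26 and Osmotin-like protein precursor (EH664897) by -1.28 ± 0.27. GDSL-motif lipase/acylhydrolase (AM783832) had -1.10 ± 0.24 and Photosystem I reaction center subunit X psaK (AM784735) -1.01 ± 0.22. The photosynthesis list had 0 of 236 features higher and 3 lower, and its mean on leaf 20 min array 2, 11.76 log2 units, lay below the 12.36 and 12.39 of the other arrays of that time. For photosynthesis the counts adjusted over the list alone were 0 and 3, with adjusted p = 5.02e-08, and adjusted p = 0.396 with an estimated correlation. LEA proteins had 1 of 39 features higher, and the list's adjusted p of 0.0221 became adjusted p = 0.118 with an estimated correlation. In all 691 features rose and 22 fell by limma's test, 0.562% of those tested. Of the 6 named falls, all but that of Aquaporin 1 lost the call when 1 array was left out, in 5 to 14 of 18 such fits. The count of 713 was 454 without leaf 0 min array 3 and 248 in a fit of the 0 and 20 min arrays alone.

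Between 40 min and 2 h the features called in the leaf grew in number. At 40 min Avr9/Cf-9 rapidly elicited protein 111B (5.18 ± 0.44), Probable phospholipid hydroperoxide glutathione peroxidase (5.15 ± 0.31) and U-box protein (FG644248, 5.09 ± 0.35), a type of ubiquitin ligase, rose most among named features, and Drm3-like protein-like protein (-2.04 ± 0.27), Aquaporin 1 (-1.98 ± 0.23) and Auxin-induced SAUR-like protein (FG641514, -1.79 ± 0.31) fell most. At 1 h Probable phospholipid hydroperoxide glutathione peroxidase had risen by 5.51 ± 0.31, Elicitor-inducible cytochrome P450 (AM821089) by 5.30 ± 0.28 and Avr9/Cf-9 rapidly elicited protein 111B by 5.08 ± 0.44. Among the named falls at 1 h Aquaporin 1 had changed by -2.30 ± 0.23, Drm3-like protein-like protein (TC34803) by -3.08 ± 0.27 and Drm3-like protein (FG633442) by -2.33 ± 0.37. At 2 h the largest named rises, below the 7.48 of the highest feature of all, were Jasmonate ZIM-domain protein 1 (TC19548), a repressor in jasmonate signalling (5.46 ± 0.30), Galactinol synthase (AM844231), the entry enzyme of raffinose sugars (5.38 ± 0.34), and WRKYnew86 (5.21 ± 0.27). The largest named falls at 2 h were Snakin2 precursor (TC15513, -3.37 ± 0.29), named after an antimicrobial peptide, Gip1 protein (CV016979, -3.20 ± 0.23) and an Auxin-induced SAUR-like protein (FG640144, -3.12 ± 0.37). All of these changes had an adjusted p below 0.05. The features higher and lower numbered 2562 and 562 at 40 min, 2610 and 710 at 1 h and 5344 and 2032 at 2 h. The 40 min count of 3124 was 1943 without leaf 40 min array 1, 2071 without leaf 40 min array 3 and 5185 with array weights, and the 2 h count of 7376 was 4345 in a fit of the 0 min and 2 h arrays alone.

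After 4 h of drying the largest named rises of the leaf included transcripts for proteins that protect dehydrating cells. Dehydrin Rab16D (AM846562) rose by 7.27 ± 0.30 (155-fold, adjusted p = 1.63e-11), from a mean log2 intensity of 7.70 ± 0.36 at 0 min to 14.98 ± 0.58 (SD). Late embryogenesis abundant protein (TC15349) rose by 6.36 ± 0.40 (82.1-fold), Low-temperature-induced 65 kDa protein (TC22382) by 6.36 ± 0.39 (82.1-fold) and Abscisic acid and environmental stress-inducible protein TAS14 (TC32910), a dehydrin, by 6.15 ± 0.52 (71-fold). Over the list of LEA proteins and dehydrins 18 of 39 features rose, 1 fell and 20 did not pass the test. For LEA proteins and dehydrins the counts adjusted over the list alone were 21 and 2, with adjusted p = 2.26e-17, and adjusted p = 2.66e-05 with an estimated correlation. Galactinol synthase (AM844231) rose by 6.83 ± 0.34 (114-fold), and compatible solute metabolism had 10 of 41 features higher and 2 lower, 4 of the rises being of Delta-1-pyrroline-5-carboxylate synthetase, which makes proline. For compatible solute metabolism the counts adjusted over the list alone were 12 and 3, with adjusted p = 5.47e-05, and adjusted p = 0.0159 with an estimated correlation. Water channels went both ways: of 81 aquaporin features 17 rose, 14 fell and 50 did not pass, with a median change of -0.22, a mean of 0.54 and a test leaning higher. For aquaporins the counts adjusted over the list alone were 20 and 19, with adjusted p = 0.0967, and adjusted p = 0.396 with an estimated correlation. Plasma intrinsic protein 2,1 (TC36051) rose by 6.54 ± 0.31 (93.3-fold), Aquaporin 2 (EB446671) by 5.99 ± 0.57, Probable aquaporin TIP-type RB7-5A (TC17859) by 5.52 ± 0.32 and Probable aquaporin TIP-type RB7-18C (TC25247) by 5.40 ± 0.21, while Aquaporin 1 fell by 0.75 (SE 0.23, adjusted p = 0.0346). Among epidermis, vascular and root-hair markers 18 of 79 features rose and 1 fell. For epidermis, vascular and root-hair markers the counts adjusted over the list alone were 19 and 4, with adjusted p = 0.000228, and adjusted p = 0.0774 with an estimated correlation. Of the 18 rises 8 carried the name Non-specific lipid-transfer protein and 8 Non-specific lipid-transfer protein 2 precursor (EB681927, 5.38 ± 0.34), a class abundant in the epidermis.

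Several lists of hormone and regulatory genes held more rises than falls in the leaf at 4 h. Jasmonate synthesis and signalling had 29 of 68 features higher and 3 lower, led by Jasmonate ZIM-domain protein 1 at 5.89 ± 0.30 (59.5-fold), with Lipoxygenase, the enzyme at the start of jasmonate synthesis, at 4.73 ± 0.29 (TC39011). For jasmonate synthesis and signalling the counts adjusted over the list alone were 30 and 4, with adjusted p = 1.67e-17, and adjusted p = 0.00183 with an estimated correlation. In ABA signalling 12 of 44 features rose and 2 fell, and 8 of the rises were of Protein phosphatase 2C, a class that holds negative regulators of the hormone's signal (AM785085, 4.10 ± 0.28). For ABA signalling the counts adjusted over the list alone were 13 and 3, with adjusted p = 5.75e-05, and adjusted p = 0.00876 with an estimated correlation. In ABA synthesis and breakdown 5 of 13 features rose and 0 fell, all 5 of them ABA 8'-hydroxylase CYP707A1 (TC25379, 4.65 ± 0.30). For ABA synthesis and breakdown the counts adjusted over the list alone were 7 and 1, with adjusted p = 2.43e-08, and adjusted p = 0.000909 with an estimated correlation. Ethylene synthesis had 9 of 39 features higher and 1 lower. For ethylene synthesis the counts adjusted over the list alone were 9 and 1, with adjusted p = 0.0246, and adjusted p = 0.153 with an estimated correlation. WRKY factors had 73 of 173 higher and 6 lower, with WRKYnew86 at 5.67 ± 0.27. For WRKY factors the counts adjusted over the list alone were 78 and 9, with adjusted p = 6.37e-20, and adjusted p = 0.00183 with an estimated correlation. AP2/ERF factors had 31 of 77 higher and 6 lower. For AP2/ERF factors the counts adjusted over the list alone were 34 and 8, with adjusted p = 3.04e-14, and adjusted p = 0.0089 with an estimated correlation. NAC factors, another family of stress regulators, had 13 of 39 higher and 0 lower, with Nam-like protein 3 (AM807127) at 4.10 ± 0.24. For NAC factors the counts adjusted over the list alone were 16 and 0, with adjusted p = 6.6e-10, and adjusted p = 0.00185 with an estimated correlation. MYB factors had 14 of 62 higher and 5 lower. For MYB factors the counts adjusted over the list alone were 15 and 8, with adjusted p = 0.0754, and adjusted p = 0.225 with an estimated correlation.

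Lists of photosynthesis, ribosomal, cell cycle and heat shock genes held more falls than rises in the leaf at 4 h. Photosynthesis had 41 of 236 features lower and 2 higher, with Photosystem I subunit XI at -1.72 ± 0.26. Its mean on leaf 4 h array 3, 12.44 log2 units, lay above the 11.96 and 12.02 of the other arrays of that time and within the 12.34 to 12.68 of 0 min. For photosynthesis the counts adjusted over the list alone were 48 and 2, with adjusted p = 7.74e-06, and adjusted p = 0.323 with an estimated correlation. Ribosomal proteins had 76 of 609 lower and 5 higher. For ribosomal proteins the counts adjusted over the list alone were 89 and 5, with adjusted p = 2.63e-08, and adjusted p = 0.019 with an estimated correlation. Cell cycle and histones had 41 of 172 lower and 3 higher, 8 of the falls being of Histone H1, and Histone H1D (EB425586) changed by -1.90 ± 0.34. For cell cycle and histones the counts adjusted over the list alone were 50 and 4, with adjusted p = 7.55e-08, and adjusted p = 0.0922 with an estimated correlation. Heat shock proteins and factors had 21 of 137 lower and 2 higher. For heat shock proteins and factors the counts adjusted over the list alone were 28 and 3, with adjusted p = 0.000339, and adjusted p = 0.0737 with an estimated correlation. The largest named falls were Gip1 protein (-4.45 ± 0.23, adjusted p = 3.07e-10), Snakin2 precursor (-3.69 ± 0.29), Glycine rich protein-interacting protein (-3.65 ± 0.24) and RNA-binding glycine-rich protein-1 (TC18024, -3.22 ± 0.41). The other 8 named falls were Drm3-like protein-like protein (TC34803), GDSL-motif lipase/acylhydrolase (TC25262, another feature than at 20 min), Catalase isozyme 1 (EB448074), BZIP transcription factor bZIP50 (TC37952), DVL14 (AM801804), Aluminum-induced protein (FG641245), Auxin-induced SAUR-like protein (FG640144) and F-box family protein-related (DW003353), with changes from -2.91 to -2.36.

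Several lists held rises and falls in the leaf at 4 h. Cell wall loosening had 19 of 140 features higher and 12 lower, with Expansin (EB426609), a wall-loosening protein, at 3.80 ± 0.23. For cell wall loosening the counts adjusted over the list alone were 19 and 15, with adjusted p = 0.0229, and adjusted p = 0.268 with an estimated correlation. Pathogenesis-related genes had 23 of 138 higher and 16 lower, with Elicitor inducible beta-1,3-glucanase NtEIG-E76 (TC15708) at 3.67 ± 0.25 and 3 Osmotin precursor features lower. For pathogenesis-related genes the counts adjusted over the list alone were 26 and 21, with adjusted p = 0.131, and adjusted p = 0.396 with an estimated correlation. Redox enzymes had 32 of 280 higher and 26 lower, among them Probable phospholipid hydroperoxide glutathione peroxidase at 4.92 ± 0.31 and Catalase isozyme 1 at -2.87 ± 0.25. For redox enzymes the counts adjusted over the list alone were 36 and 30, with adjusted p = 0.205, and adjusted p = 0.334 with an estimated correlation. Housekeeping genes had 12 of 150 higher and 10 lower, their median change was -0.03 and their mean 0.05 with a test leaning higher, and 10 of the 12 rises were of Polyubiquitin. For housekeeping genes the counts adjusted over the list alone were 12 and 11, with adjusted p = 0.587, and adjusted p = 0.831 with an estimated correlation. Nicotine synthesis had 1 of 28 higher and 0 lower, the rise being of Berberine bridge enzyme like protein (TC20599, 0.90 ± 0.26), and its median of 0.00521 was -0.00112 after quantile normalization. For nicotine synthesis the counts adjusted over the list alone were 0 and 0, with adjusted p = 0.379, and adjusted p = 0.567 with an estimated correlation. Organelle-encoded genes and rRNA had 1 of 72 higher and 1 lower. For organelle-encoded genes and rRNA the counts adjusted over the list alone were 1 and 1, with adjusted p = 0.0967, and adjusted p = 0.465 with an estimated correlation. In all 7622 features rose and 7514 fell at 4 h, 11.9% of those tested, and 9964 of these changes were of at least 2-fold. The F test over all times called 15158 features in the leaf.

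**Figure D1:**
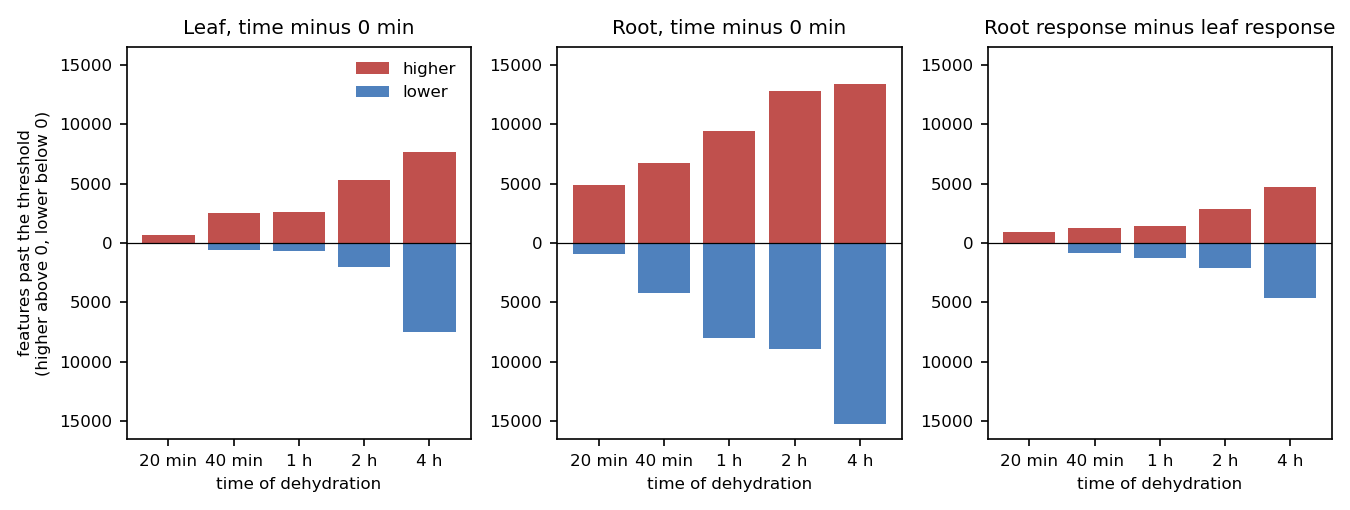
Number of features past an adjusted p of 0.05 in limma's test at each time of dehydration, with features higher above 0 and lower below 0, for the leaf, the root and the difference of their responses. The counts grew from 713 to 15136 in the leaf and from 5778 to 28603 in the root, and those of the difference from 1067 to 9346.

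The root series asked the same of the organ that had lost its water supply, and at 20 min the largest named rises included those of transcription factors, while the largest rise of any feature was 7.78. Wound-responsive AP2 like factor 2 (FG642600) rose by 6.50 ± 0.45 (90.8-fold, adjusted p = 1.46e-07), from a mean log2 intensity of 5.34 ± 0.45 to 11.85 ± 0.32 (SD). GmMYB29B2 protein (DW002203), a MYB factor by name, rose by 5.77 ± 0.33 (54.6-fold), Wound-responsive AP2 like factor 1 (FG642660) by 5.38 ± 0.22 and RAP2-like protein (FG642636) by 5.34 ± 0.49. The zinc finger ZPT2-13 (CV021744) rose by 4.70 ± 0.26 and Avirulence-like protein 1 (TC17594) by 4.63 ± 0.40. The list of AP2/ERF factors had 40 of 77 features higher and 1 lower, and WRKY factors had 78 of 173 higher and 1 lower. The list of AP2/ERF factors had 47 and 1 adjusted over the list alone, with adjusted p = 8.99e-41, and adjusted p = 0.012 with an estimated correlation. The list of WRKY factors had 96 and 1 adjusted over the list alone, with adjusted p = 7.51e-44, and adjusted p = 0.012 with an estimated correlation. Ethylene synthesis had 11 of 39 higher and 0 lower, 6 of the rises being of 1-aminocyclopropane-1-carboxylate synthase, the enzyme that makes ethylene's precursor (AM806812, 2.02 ± 0.33). The list of ethylene synthesis had 15 and 0 adjusted over the list alone, with adjusted p = 8.6e-09, and adjusted p = 0.017 with an estimated correlation. Jasmonate synthesis and signalling had 18 of 68 higher and 0 lower, with Jasmonate ZIM-domain protein 1 at 3.37 ± 0.27 and Allene oxide synthase at 4.47 ± 0.33 (TC36042). The list of jasmonate synthesis and signalling had 24 and 2 adjusted over the list alone, with adjusted p = 2.33e-13, and adjusted p = 0.107 with an estimated correlation. NAC factors had 13 of 39 higher and 0 lower. The list of NAC factors had 19 and 0 adjusted over the list alone, with adjusted p = 4.12e-12, and adjusted p = 0.071 with an estimated correlation. In ABA synthesis and breakdown 5 of 13 rose and 0 fell, again all ABA 8'-hydroxylase CYP707A1. The list of ABA synthesis and breakdown had 5 and 0 adjusted over the list alone, with adjusted p = 2.14e-08, and adjusted p = 0.071 with an estimated correlation.

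The named falls of the root at 20 min were smaller. CYP1 (AM835825) changed by -2.39 ± 0.28 and Small molecular heat shock protein 10 (BP531158) by -2.39 ± 0.25. Molecular chaperone Hsp90-2 (EB432336) changed by -2.32 ± 0.27, Glutathione S-transferase/peroxidase (AM794685) by -2.16 ± 0.30, Aquaporin 1 by -2.01 ± 0.24 and Aquaporin (TC33307) by -1.80 ± 0.34. Of the 81 aquaporin features 2 fell and 0 rose. The list of aquaporins had 2 and 0 adjusted over the list alone, with adjusted p = 1.5e-06, and adjusted p = 0.359 with an estimated correlation. In all 4890 features rose and 888 fell, 4.55% of those tested, and the count of 5778 was 18753 with array weights.

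At 40 min, 1 h and 2 h GmMYB29B2 protein and Wound-responsive AP2 like factor 2 stayed among the 3 largest named rises of the root. They stood at 6.85 ± 0.33 and 7.04 ± 0.45 at 40 min, at 6.84 ± 0.33 and 6.55 ± 0.45 at 1 h and at 6.33 ± 0.33 and 7.16 ± 0.45 at 2 h. The other was Wound-responsive AP2 like factor 1 (TC25453) at 40 min (5.72 ± 0.28), Allene oxide synthase, a step of jasmonate synthesis, at 1 h (5.39 ± 0.33), and Late embryogenesis abundant protein at 2 h (7.62 ± 0.29). The named falls at 40 min were CYP1 (-2.23), Small molecular heat shock protein 10 (-2.26) and Molecular chaperone Hsp90-2 (-2.16). At 1 h they were Catalase isozyme 1 (TC34928, -2.96), Glycine rich protein-interacting protein (-2.61) and Non-symbiotic hemoglobin 1 (TC20396), an oxygen-binding protein (-2.37). At 2 h they were CYP72A57 (AM819711, -3.59), RNA-binding glycine-rich protein-1 (-3.57) and Non-symbiotic hemoglobin 1 (-3.49). Features higher and lower numbered 6756 and 4201 at 40 min, 9414 and 7993 at 1 h and 12814 and 8930 at 2 h. The 40 min count of 10957 was 6064 to 7277 without root 0 min array 1, 2 or 3 or root 40 min array 2, and the 1 h count of 17407 was 10150 to 10516 without root 0 min array 2 or 3 or root 1 h array 1 or 2. With array weights the counts were 24171 at 40 min, 58242 at 1 h and 40091 at 2 h, against 10957, 17407 and 21744 without.

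At 4 h the largest named rises of the root included those of protective proteins and transcription factors. Late embryogenesis abundant protein rose by 7.74 ± 0.29 (214-fold, adjusted p = 3.9e-10), from a mean log2 intensity of 4.73 ± 0.19 to 12.47 ± 0.16 (SD), and Wound-responsive AP2 like factor 2 (FG642600) by 7.0 ± 0.45 (128-fold). The 0 min level of Late embryogenesis abundant protein lay near the random probes of those arrays (17.96 to 19.65 intensity units), so its fold is imprecise. GmMYB29B2 protein rose by 6.24 ± 0.33, WRKYnew57 by 5.62 ± 0.29, Biotic cell death-associated protein (TC15278) by 5.51 ± 0.85 and Abscisic acid and environmental stress-inducible protein TAS14 by 5.45 ± 0.30. The other 6 named rises, Wound-responsive AP2 like factor 1 (FG642660), WRKYnew63, Allene oxide synthase (BP528515), TINY-like protein (AM812561), Dehydrin (TC15388) and S-adenosylmethionine synthetase (TC32668), ranged from 5.04 to 5.32. S-adenosylmethionine synthetase, with a mean log2 intensity of 4.49 at 0 min, also lay near the random probes, so its fold is imprecise too. LEA proteins and dehydrins had 22 of 39 features higher and 0 lower. The list of LEA proteins and dehydrins had 22 and 2 adjusted over the list alone, with adjusted p = 9.48e-12, and adjusted p = 0.0659 with an estimated correlation. Jasmonate synthesis and signalling had 34 of 68 higher and 8 lower, including all 7 features of Jasmonate ZIM-domain protein 1. The list of jasmonate synthesis and signalling had 37 and 9 adjusted over the list alone, with adjusted p = 5.54e-11, and adjusted p = 0.152 with an estimated correlation. Ethylene synthesis had 19 of 39 higher and 3 lower, with 1-aminocyclopropane-1-carboxylate synthase (AM806812) at 4.89 ± 0.33. The list of ethylene synthesis had 21 and 3 adjusted over the list alone, with adjusted p = 9.48e-08, and adjusted p = 0.0523 with an estimated correlation. WRKY factors had 99 of 173 higher and 15 lower, AP2/ERF factors 40 of 77 and 8, and NAC factors 18 of 39 and 5. The list of WRKY factors had 106 and 15 adjusted over the list alone, with adjusted p = 3.5e-25, and adjusted p = 0.0523 with an estimated correlation. The list of AP2/ERF factors had 44 and 10 adjusted over the list alone, with adjusted p = 1.02e-14, and adjusted p = 0.145 with an estimated correlation. The list of NAC factors had 20 and 7 adjusted over the list alone, with adjusted p = 1.92e-07, and adjusted p = 0.152 with an estimated correlation.

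Features of the ABA and solute lists rose in the root as well. In ABA signalling 17 of 44 features rose and 3 fell at 4 h, 9 of the rises being of Protein phosphatase 2C (AM785085, 4.29 ± 0.23). The list of ABA signalling had 17 and 4 adjusted over the list alone, with adjusted p = 0.000251, and adjusted p = 0.152 with an estimated correlation. In ABA synthesis and breakdown 6 of 13 rose and 0 fell, 3 of ABA 8'-hydroxylase CYP707A1 and 3 of Zeaxanthin epoxidase, an enzyme of ABA synthesis. The Zeaxanthin epoxidase rises were small, 0.968 (TC20597), 0.898 (TC25909) and 0.782 (TC18361). Without root 2 h array 1 and root 4 h array 1, which stand apart, TC20597 (0.937, adjusted p = 0.102) and TC25909 (0.844, adjusted p = 0.112) lost the call of limma's test, while TC18361 kept it. The list of ABA synthesis and breakdown had 8 and 0 adjusted over the list alone, with adjusted p = 0.00191, and adjusted p = 0.314 with an estimated correlation. Compatible solute metabolism had 9 of 41 higher and 2 lower, with Galactinol synthase (FG645510) at 2.72 ± 0.14 and Trehalose-6-phosphate synthase like protein (BP132726) at 2.40 ± 0.35. The list of compatible solute metabolism had 9 and 2 adjusted over the list alone, with adjusted p = 0.00249, and adjusted p = 0.152 with an estimated correlation. Pathogenesis-related genes had 27 of 138 higher and 7 lower, with all 5 features of Class IV chitinase higher and Thaumatin-like protein SE39b (TC20291) at 4.43 ± 0.29. The list of pathogenesis-related genes had 27 and 7 adjusted over the list alone, with adjusted p = 0.0103, and adjusted p = 0.646 with an estimated correlation. Epidermis, vascular and root-hair markers had 10 of 79 higher and 4 lower. The list of epidermis, vascular and root-hair markers had 9 and 4 adjusted over the list alone, with adjusted p = 0.0516, and adjusted p = 0.647 with an estimated correlation.

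The largest named falls of the root at 4 h were RNA-binding glycine-rich protein-1 (-4.57 ± 0.27, adjusted p = 1.26e-08), CYP72A57 (-4.45 ± 0.40), Aquaporin (TC33307, -3.83 ± 0.34) and Non-symbiotic hemoglobin 1 (-3.69 ± 0.54). The other 8 named falls were Glycine rich protein-interacting protein (TC28122), Glutathione S-transferase/peroxidase, Cytochrome P450 71A4 (TC31614), CYP82M1v1 (TC22779), Ethphon-induced protein (TC18367), HMG type nucleosome/chromatin assembly factor D (EB444563), Homeodomain protein Hfi22 (AM797379) and TRNA-Tyr protein (BP526550), with changes from -3.39 to -2.71. Aquaporins had 23 of 81 features lower and 11 higher. The list of aquaporins had 28 and 12 adjusted over the list alone, with adjusted p = 0.0516, and adjusted p = 0.769 with an estimated correlation. Heat shock proteins and factors had 29 of 137 lower and 12 higher, and 5 of the rises were of Heat shock factor while Heat shock protein 26 (TC19476) stood at 3.81 ± 0.25. The list of heat shock proteins and factors had 31 and 12 adjusted over the list alone, with adjusted p = 0.00652, and adjusted p = 0.646 with an estimated correlation. Ribosomal proteins had 52 of 609 lower and 22 higher. Of all 126892 features 15241 were lower and 13362 higher, so ribosomal proteins were called less often than features at large in both directions. The list of ribosomal proteins had 17 and 13 adjusted over the list alone, with adjusted p = 0.00109, and adjusted p = 0.647 with an estimated correlation. Cell cycle and histones had 25 of 172 lower and 8 higher, with a share of falls near that of all features. The list of cell cycle and histones had 23 and 8 adjusted over the list alone, with adjusted p = 0.00032, and adjusted p = 0.647 with an estimated correlation. MYB factors, a list without GmMYB29B2 protein, had 17 of 62 lower and 5 higher. The list of MYB factors had 17 and 6 adjusted over the list alone, with adjusted p = 0.23, and adjusted p = 0.757 with an estimated correlation.

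Other lists of the root at 4 h were mixed. Redox enzymes had 42 of 280 features higher and 35 lower, with a median of -0.04, a mean of 0.02, a test leaning higher and all 6 features of Catalase isozyme 1, which removes hydrogen peroxide, lower. The list of redox enzymes had 43 and 35 adjusted over the list alone, with adjusted p = 0.586, and adjusted p = 0.912 with an estimated correlation. Cell wall loosening had 25 of 140 higher and 28 lower, with 5 features each of XTH9 and XTH3 higher and 5 of Pectate lyase lower. The list of cell wall loosening had 28 and 32 adjusted over the list alone, with adjusted p = 0.52, and adjusted p = 0.912 with an estimated correlation. Photosynthesis had 5 of 236 higher and 10 lower, and its mean on root 4 h array 1 was 10.38 log2 units against 9.27 and 8.95 on the other arrays of that time. The list of photosynthesis had 0 and 3 adjusted over the list alone, with adjusted p = 0.958, and adjusted p = 0.988 with an estimated correlation. Nicotine synthesis, an activity of tobacco roots, had 0 of 28 higher and 2 lower, both of N-methylputrescine oxidase (TC18608, -0.69 ± 0.20), with a median of 0.00517, a mean of -0.06 and a test leaning higher. Its mean log2 intensity in the root at 0 min was already 14.2, against a highest value of 16 on the root arrays, which limits the room for rises. The list of nicotine synthesis had 0 and 0 adjusted over the list alone, with adjusted p = 0.966, and adjusted p = 0.988 with an estimated correlation. Housekeeping genes had 7 of 150 higher and 16 lower. The list of housekeeping genes had 6 and 13 adjusted over the list alone, with adjusted p = 0.0994, and adjusted p = 0.736 with an estimated correlation. Organelle-encoded genes and rRNA had 3 of 72 higher and 7 lower, with a median of 0.04 and a test leaning lower. The list of organelle-encoded genes and rRNA had 2 and 7 adjusted over the list alone, with adjusted p = 0.958, and adjusted p = 0.988 with an estimated correlation. In all 13362 features rose and 15241 fell, 22.5% of those tested, 13574 of them by at least 2-fold, and the F test over all times called 31547. With array weights these counts were 43842 at 4 h and 95405 for the F test. No list of the root kept its call at 1 h or 4 h once the correlation was estimated.

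**Figure D2:**
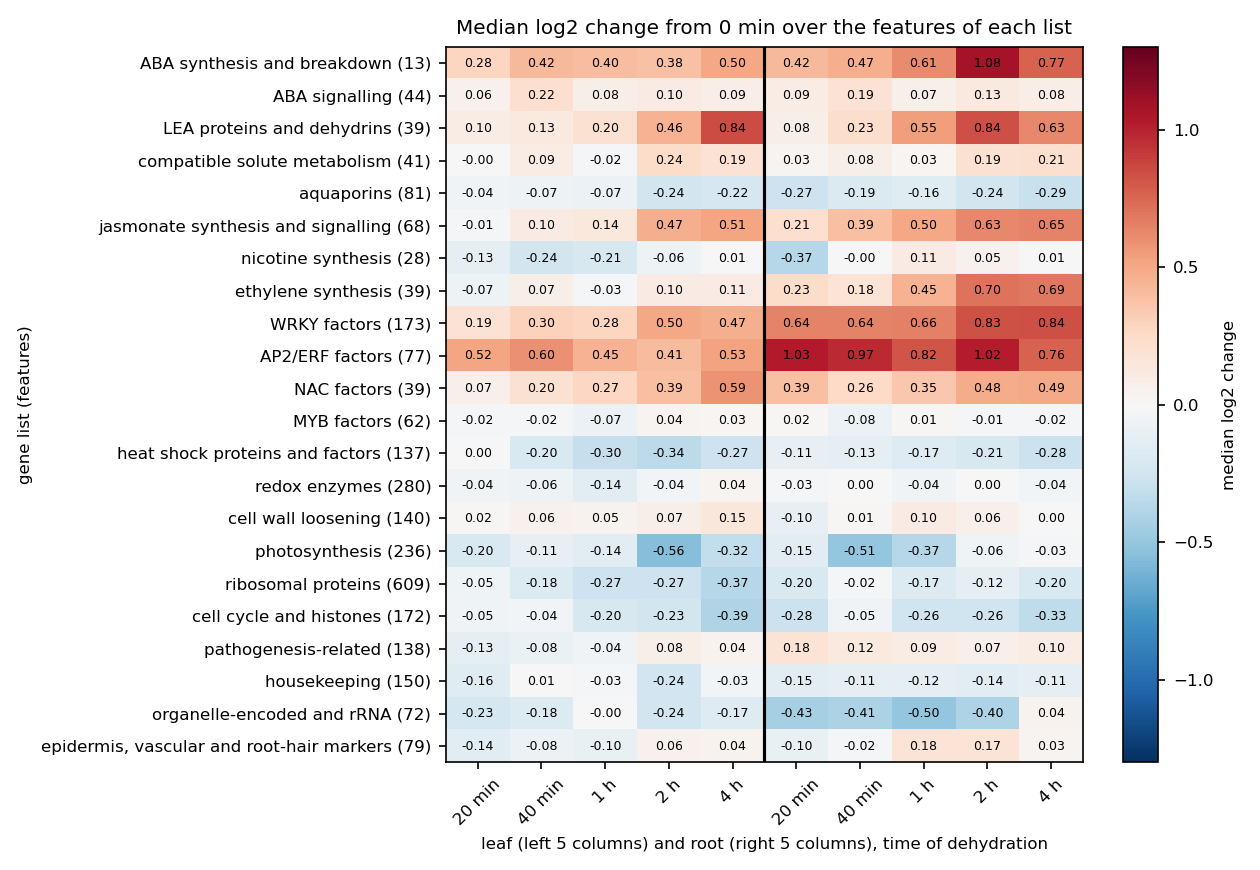
Median log2 change from 0 min over the features of each of 22 gene lists, at 5 times in the leaf (left) and the root (right), with the number of features in brackets and the median printed in each cell. LEA proteins and dehydrins reached medians of 0.84 in the leaf and 0.63 in the root at 4 h, and AP2/ERF factors stood at 0.52 and 1.03 at 20 min.

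**Figure D3:**
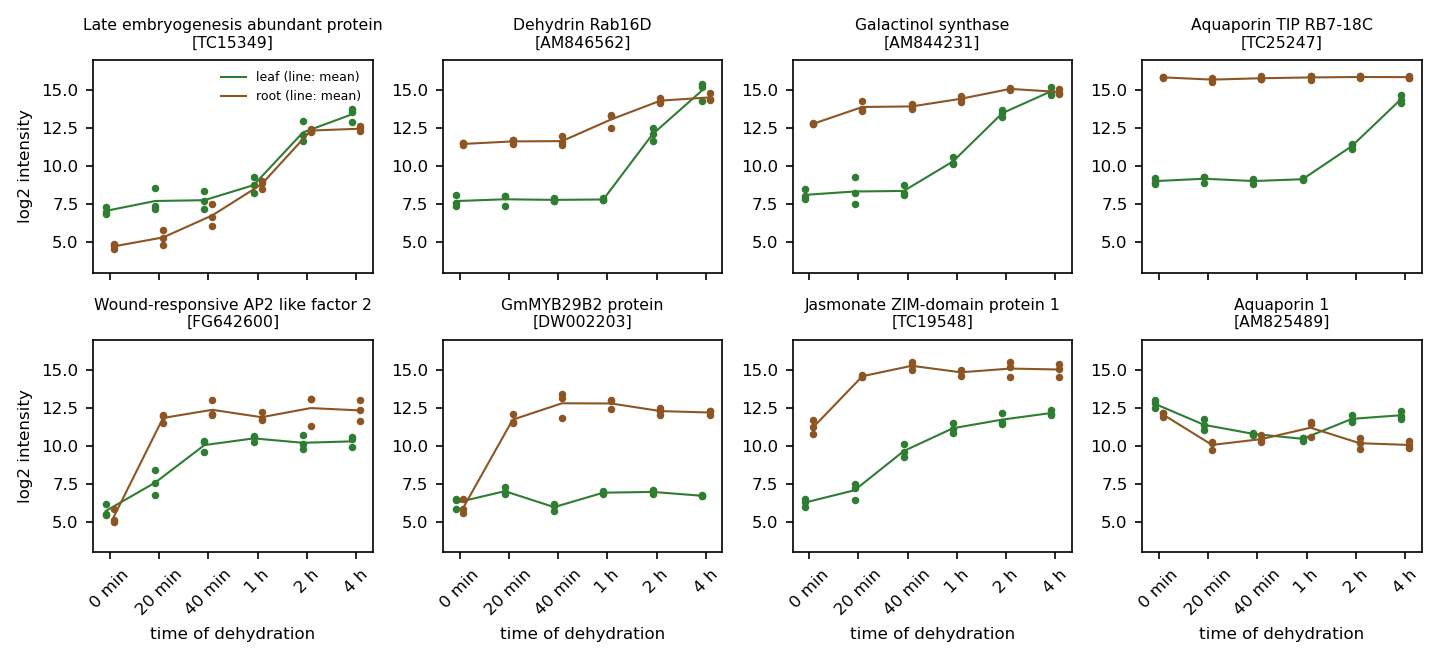
Log2 intensity of 8 named features over time, with each array as a point and the mean of 3 arrays as a line, in the leaf (green) and the root (brown). Probable aquaporin TIP-type RB7-18C rose by 5.40 in the leaf at 4 h and GmMYB29B2 protein by 6.24 in the root.

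The tissues were compared to ask which responses leaf and root shared. Nearly every feature that rose in the leaf at 20 min also rose in the root: 661 of 691 (95.7%), against 26.6 for independent lists of those sizes (odds ratio 633, Fisher's exact test). Among the named genes, the rises shared at 4 h included Late embryogenesis abundant protein (6.36 in the leaf, 7.74 in the root), Abscisic acid and environmental stress-inducible protein TAS14 (6.15 and 5.45) and Biotic cell death-associated protein (4.80 and 5.51). The falls shared included RNA-binding glycine-rich protein-1 (-3.22 and -4.57) and Glycine rich protein-interacting protein (-3.65 and -3.39). At 4 h 4610 features rose in both tissues, 60.5% of the leaf's rises, against 803 for independent lists (odds ratio 19.3), and 3197 fell in both, 42.5% of the leaf's falls, against 903 (odds ratio 6.6). Shared rises numbered 1921 at 40 min, 1946 at 1 h and 3934 at 2 h, and shared falls 5 at 20 min, 63 at 40 min, 274 at 1 h and 787 at 2 h. Each of the 10 overlaps exceeded that of independent lists by Fisher's exact test (2-sided, largest adjusted p = 3.96e-07, n = 126892 features), in which features of one gene family are not independent. Opposite calls were fewer at 4 h, 203 higher in the leaf and lower in the root and 218 the other way, against 915 and 791 for independent lists.

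The difference of the responses, root minus leaf, was tested in a fit of both tissues. At 20 min the named features that differed most were GmMYB29B2 protein, at 5.0 ± 0.39 (adjusted p = 8.75e-09), Wound-responsive AP2 like factor 2 at 4.64 ± 0.59 (adjusted p = 1.68e-05) and Avr9/Cf-9 rapidly elicited protein 75 (TC25975) at 4.19 ± 0.41 (adjusted p = 3.08e-07). In the other direction stood Small molecular heat shock protein 10 at -2.28 ± 0.47 (adjusted p = 0.00834), Glutathione S-transferase/peroxidase at -2.22 ± 0.44 (adjusted p = 0.00577) and Chaperonin CPN60-2, mitochondrial precursor (BP130657) at -2.04 ± 0.34 (adjusted p = 0.000851). Jasmonate synthesis and signalling had 13 of 68 features with a higher response in the root and 0 with a lower, and AP2/ERF factors had 9 of 77 and 0. The test of jasmonate synthesis and signalling gave adjusted p = 7.6e-17, and adjusted p = 0.0157 with an estimated correlation, with counts of 19 and 1 adjusted over the list alone. The test of AP2/ERF factors gave adjusted p = 2.89e-12, and adjusted p = 0.0372 with an estimated correlation, with counts of 16 and 0 adjusted over the list alone. At 4 h GmMYB29B2 protein differed by 5.78 ± 0.39 (adjusted p = 3.33e-11), CP12 precursor (TC20069), a regulator of carbon fixation, by 5.50 ± 0.49 (adjusted p = 7.18e-09) and WRKYnew57 by 5.48 ± 0.48 (adjusted p = 5.13e-09). CP12 precursor rose by 5.02 ± 0.38 in the root, and by 4.94 (adjusted p = 5.67e-06) without root 2 h array 1 and root 4 h array 1, which had the highest photosynthesis means of the root. Aquaporin 2 at -5.59 ± 0.66 (adjusted p = 7.6e-07), Plasma intrinsic protein 2,1 at -5.48 ± 0.67 (adjusted p = 1.39e-06) and Probable aquaporin TIP-type RB7-5A at -5.48 ± 0.39 (adjusted p = 6.37e-11) rose more in the leaf, and in the root they stood at mean log2 intensities of 13.43 ± 0.08, 9.09 ± 0.08 and 14.83 ± 0.09 (SD) at 0 min. Probable aquaporin TIP-type RB7-18C stood at 15.85 ± 0.02 there. The highest intensity on any root array was 65398, so Aquaporin 2, RB7-5A and RB7-18C could not have risen in the root by as much as in the leaf, and the sizes of their differences are to be read with that ceiling. Plasma intrinsic protein 2,1 (TC36051) had room for such a rise. Another feature of that name (TC21439) did not, with a leaf rise of 6.35 and room for 2.57 in the root. Over the aquaporin list 16 of 81 features responded higher in the leaf and 1 higher in the root. The test of aquaporins gave adjusted p = 1.52e-05, and adjusted p = 0.401 with an estimated correlation, with counts of 18 and 2 adjusted over the list alone. Of the 16 features 8 had less room in the root than their rise in the leaf, 7 had room for it and 1 had a negative change in the leaf, so the ceiling limits the count and the test of this list as well. Ethylene synthesis had 11 of 39 with a higher response in the root and 1 in the leaf. The test of ethylene synthesis gave adjusted p = 1.52e-05, and adjusted p = 0.0845 with an estimated correlation, with counts of 15 and 2 adjusted over the list alone. Features higher and lower in the root response numbered 967 and 100 at 20 min, 1301 and 842 at 40 min, 1432 and 1231 at 1 h, 2898 and 2107 at 2 h, and 4690 and 4656 at 4 h. The count of 1067 at 20 min was 619 without root 20 min array 3, that of 2143 at 40 min was 1134 to 1387 without leaf 40 min array 3, root 0 min array 1, 2 or 3, or root 40 min array 2 or 3, and 4019 without root 40 min array 1, and that of 2663 at 1 h was 1582 without root 1 h array 1, 1653 without root 0 min array 2 and 4900 without root 1 h array 3. With array weights the counts were 2065 at 20 min, 9499 at 40 min, 14491 at 1 h and 7810 at 2 h, where a fit of the groups compared gave 3258 and leaving out the dimmest 33.3% of features gave 3297.

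**Figure D4:**
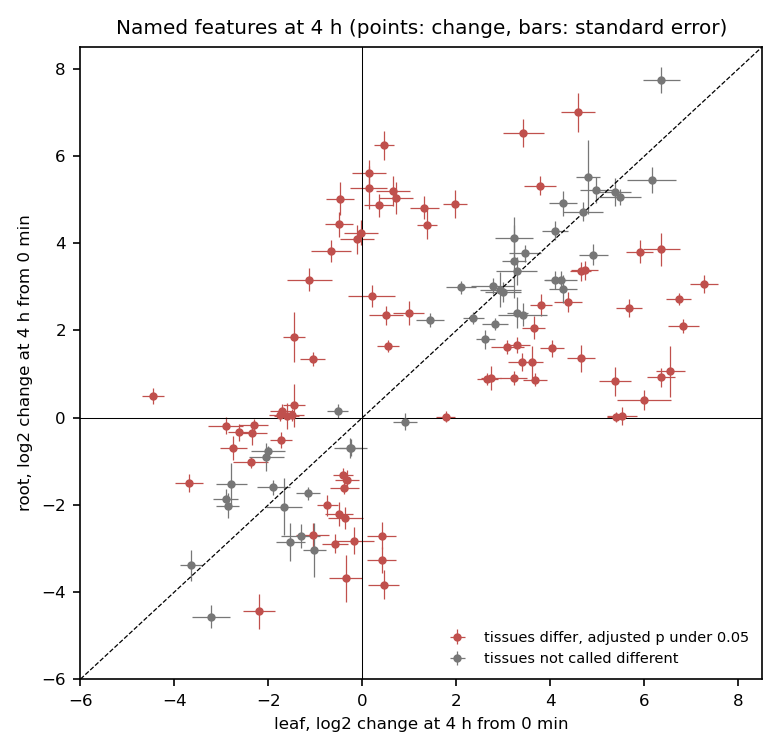
Log2 change at 4 h from 0 min in the leaf (horizontal axis) and the root (vertical axis) for the 124 named features, with standard errors as bars and the dashed line marking equal change. The tissues' changes differed by the test of the difference for 80 of them, among them Aquaporin 2 at 5.99 in the leaf, and were not called different for 44. The features were picked by large changes, small p or large differences between tissues, which favours a high share. Over all features 7.37% differed at 4 h.

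Early rises were set against those at 4 h to ask how far the first response persisted. Avr9/Cf-9 rapidly elicited protein 20 (TC20908) stood at 3.55 in the leaf at 20 min and at 0.20 with adjusted p = 0.896 at 4 h, the lowest of the features of that name, of which the others stood at 0.31 to 1.34. Protein 231 precursor (TC23903) and 111B were still at 2.77 and 3.28 at 4 h. Jasmonate ZIM-domain protein 1, at 0.81 (adjusted p = 0.655) at 20 min, stood at 5.89 at 4 h. Of the 691 features that rose in the leaf at 20 min, 543 (78.6%) also rose at 4 h and 3 fell. In the root 3897 of 4890 (79.7%) also rose at 4 h and 43 fell. Independent lists would share 41.5 and 515. Groups simulated with no change had 0 calls and so shared 0, which sets no level for the part that the shared 0 min arrays add. Both comparisons used the same 0 min arrays, which are too few to split, so part of the excess may come from them. The covariance of the changes at 20 min and 4 h across features was 0.0683 in the leaf against 0.049 simulated for unchanged groups, and 0.185 against 0.0343 in the root. The correlation across features, which are not independent replicates, was 0.272 in the leaf against 0.503 simulated, and 0.519 against 0.496 in the root.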

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

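The nicotine synthesis test in the part on aquaporins, the size of the moves by the scalings, the room of aquaporins below the array ceiling, the size of the changes of plastid protein features that lost the call and the separate count of splits that mixed the times in both tissues were chosen only after the results were seen. The results given here are those for which the change in the root differed from the change in the leaf by limma's test of that difference. The features that differed numbered 1067 at 20 min, 2143 at 40 min, 2663 at 1 h, 5005 at 2 h and 9346 at 4 h. At 20 min the root minus leaf difference of log2 change was 5.0 for GmMYB29B2 protein, 4.64 for Wound-responsive AP2 like factor 2 and 4.19 for Avr9/Cf-9 rapidly elicited protein 75. It was -2.28 for Small molecular heat shock protein 10, -2.22 for Glutathione S-transferase/peroxidase and -2.04 for Chaperonin CPN60-2, mitochondrial precursor. At 4 h it was 5.78 for GmMYB29B2 protein, 5.50 for CP12 precursor and 5.48 for WRKYnew57, and -5.59 for Aquaporin 2, -5.48 for Plasma intrinsic protein 2,1 and -5.48 for Probable aquaporin TIP-type RB7-5A, of which Aquaporin 2 and RB7-5A were too bright in the root at 0 min to rise there as much as in the leaf.

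Other groupings of the arrays were tried for each count. For the comparisons of 3 arrays with 3, all 10 splits of the 6 arrays were run, and 1, the real one, gave the real count. These splits are too few for a share under 0.05. The real counts in the leaf were 713, 3124, 3320, 7376 and 15136 from 20 min to 4 h, with 2 as the highest of other splits at 20 min and 0 at the other times. In the root they were 5778, 10957, 17407, 21744 and 28603, with 0 as the highest of other splits at each time. For the F test over all times 1 of 100 splits, the real one, gave as many features in each tissue. The counts were 15158 in the leaf against 6098 as the highest other, and 31547 in the root against 11375. Chance is thus unlikely but not excluded by 100 splits, and the splits cannot separate time from the slots of the root arrays. For the difference of tissues 6 of 50 splits at 20 min, 5 at 40 min, 5 at 1 h and 3 at 4 h gave as many features as the real one, and 2 did at 2 h. The highest other counts, 4165, 4627, 5541, 12918 and 15304, lay above the real counts, which points to a structure of the samples: these splits keep or wholly swap the times of a tissue and so still hold its response. The shares therefore follow how many such splits were drawn and settle nothing about chance at any of the times. Splits that mixed the times in both tissues numbered 41, 39, 34, 44 and 42, their highest counts were 2, 1, 0, 1785 and 0, and 0 of them reached the real count.

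The first pattern is the rise in the leaf at 4 h of 17 of 81 aquaporin features, among them Probable aquaporin TIP-type RB7-5A and RB7-18C, which are named after a root gene. Root RNA in the leaf arrays would bring the other transcripts of the root, but 531 features bright in the root and dim in the leaf had a median change of 0.0974 (quartiles -0.204 and 0.597) against 3.74 for the rising aquaporins, and the nicotine synthesis list, made in the root, had a median of 0.00521. Both argue against it. The authors' normalization stays open: 17 of 17 rising aquaporins kept the call after centring and after quantile normalization, but these moved the changes by at most 0.0252, less than the smallest rise of 0.645, so they could not have ended the pattern. Cross-hybridisation between related aquaporin sequences was not tested, and a response of leaf aquaporin genes to drying stays open as an untested explanation.

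The second pattern is that 55 of 764 features of plastid protein genes were higher in the root at 4 h, while 75 were lower, against 13362 higher and 15241 lower of all 126892, so the group did not rise as a whole. Leaf RNA on the root arrays of 4 h would raise leaf transcripts on all 3, but 312 features bright in the leaf and dim in the root had median changes of 1.2, 0.186 and -0.068 on arrays 1, 2 and 3 of 4 h, and the lowest value argues against leaf RNA on every array but leaves array 1 open. Root 4 h array 1 and root 2 h array 1 (1.33) stood apart, and 39 of the 55 rises kept the call without them. The other 16 lost it with 0.705 to 1.01 times their change left, so none rests on these arrays alone in size, while the bar set on the calls was not met and their part in the pattern stays open. A response of root plastid genes was not tested.

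The third pattern is that more features changed in the root (5778) than in the leaf (713) at 20 min. A smaller spread between root arrays is argued against, since 4468 root features were still called when tested with the spread of the leaf arrays. Brighter root arrays stay open in part. Among features in the upper 33.3% of both tissues the root count was still 4.46 times the leaf count (2416 and 542). That gap was narrower than over all features (5778 and 713), and brightness was not matched between the tissues. Leaf 20 min array 2, which stands apart, is argued against as the source of this gap. The leaf count without it was 515, although leaving out an array of the time compared also weakens the test. With 1 root array left out in turn, which weakens the root test likewise, the lowest root count was 3947 (without root 20 min array 3). A faster response of the root to drying may account for the pattern and was tested only against these explanations, on the same data, so it remains a hypothesis.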

How the results depend on the processing

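The fits without the arrays that stand apart and with the photosynthesis mean as a covariate were chosen only after the data were seen. All counts of features stayed within 1.5 times the value reported under quantile normalization, median centring, an offset of 16, a trend and robust variance, and both added fits (the covariate in the root alone), and none of the results tested under any alternative reversed. The deposited RMA values already include a quantile normalization. Quantile normalization and median centring therefore had little left to change and are weak tests of the authors' normalization. The 10 counts of calls shared by the tissues also exceeded independent lists at adjusted p under 0.01 and with a 2-fold threshold. No paired analysis was possible because replicate numbers are not tied to arrays. A slide or scan-date block and a replicate block were not run, and fits of the compared groups alone do not apply to the F tests. With only the groups compared, fewer arrays inform the spread, and the count was 248 in the leaf at 20 min, 4345 in the leaf at 2 h and 3258 for the difference at 2 h. With array weights, which ran from 0.246 to 5.34 in the root, the count was 5185 in the leaf at 40 min. It was 18753, 24171, 58242, 40091 and 43842 in the root from 20 min to 4 h, 95405 for the root F test, and 2065, 9499, 14491 and 7810 for the difference from 20 min to 2 h. The cause was not tested. An adjusted p under 0.01 passes fewer features by construction: 1853, 2202, 4463 and 9093 in the leaf from 40 min to 4 h and 8788 for its F test. It left 3837, 5763, 8200, 13635 and 18044 in the root and 18025 for its F test, and 546, 845, 1191, 2462 and 5299 for the difference. A change of at least 2-fold left 9964 in the leaf at 4 h, 3681, 5280, 7183, 11016 and 13574 in the root from 20 min to 4 h and 15921 for its F test. Without the 33.3% of features of lowest mean the difference at 2 h had 3297, with fewer features tested, and the lists called for the difference were 4 of 22 at 40 min (8 reported) and 10 at 1 h (6 reported). The cause was not tested. With an estimated correlation the lists called in the leaf were 3 at 20 min, 4 at 40 min, 9 at 2 h and 9 at 4 h. In the root they were 3, 2, 0, 3 and 0, and for the difference 5, 0, 0, 0 and 0. Estimated correlations above the preset 0.01 widen the test by construction. Leaving out each array in turn gave 454 to 734 in the leaf at 20 min (lowest without leaf 0 min array 3) and 1943 to 3736 at 40 min (lowest without leaf 40 min array 1, 2071 without array 3). In the root it gave 6064 to 15357 at 40 min and 10150 to 23197 at 1 h. For the difference it gave 619 to 1167 at 20 min (lowest without root 20 min array 3), 1134 to 4019 at 40 min and 1582 to 4900 at 1 h. The lowest root value at 40 min was without root 40 min array 2 (7155, 7277 and 6918 without root 0 min array 1, 2 or 3), and at 1 h without root 1 h array 1 (10516 without array 2, 10486 and 10431 without root 0 min array 2 or 3). For the difference at 40 min it was 1134 and 1357 without root 40 min array 2 or 3, 4019 without array 1, 1384, 1381 and 1387 without root 0 min array 1, 2 or 3, and 1372 without leaf 40 min array 3. For the difference at 1 h it was 1582 and 4900 without root 1 h array 1 or 3 and 1653 without root 0 min array 2. All 240 values of named genes stayed on their side of the threshold under quantile normalization, and those called had the same direction there and in the deposited table of 1 value per sample. That table holds the geometric mean of the same arrays, so its directions were fixed in advance. Centring ended the call of GDSL-motif lipase/acylhydrolase in the leaf at 20 min (-1.10 as reported, -1.08 with adjusted p = 0.0565), and the offset ended that call (-0.80, adjusted p = 0.0525), that of Photosystem I reaction center subunit X psaK (-0.70, adjusted p = 0.121) and that of Chlorophyll a-b binding protein 16, chloroplast precursor in the root at 4 h (1.24, adjusted p = 0.056). Of 330 tests of single lists an estimated correlation ended 128 calls, centring ended 1 and added 2, and leaving out dim features ended 13 and added 16. Signal over background limits what dim features can show: 35.0% to 36.7% of features on leaf arrays and 24.6% to 25.9% on root arrays lay under 100 intensity units, and random probes on the root arrays read 16.79 to 22.65.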

Other observations

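The test of Avr9/Cf-9 genes below was chosen only after its result was seen. At 20 min several lists differed between the responses of root and leaf beyond those already given. Ethylene synthesis had 7 of 39 features with a higher response in the root and 0 with a lower. The test of ethylene synthesis gave adjusted p = 2.84e-07, and adjusted p = 0.0157 with an estimated correlation, with counts of 8 and 0 adjusted over the list alone. WRKY factors had 17 of 173 and 0, and NAC factors 2 of 39 and 0. The test of WRKY factors gave adjusted p = 5.97e-14, and adjusted p = 0.0261 with an estimated correlation, with counts of 42 and 4 adjusted over the list alone. The test of NAC factors gave adjusted p = 6.49e-07, and adjusted p = 0.0372 with an estimated correlation, with counts of 5 and 0 adjusted over the list alone. Pathogenesis-related genes had 2 of 138 and 0. The test of pathogenesis-related genes gave adjusted p = 4.69e-07, and adjusted p = 0.0624 with an estimated correlation, with counts of 2 and 0 adjusted over the list alone. At 4 h MYB factors had 2 of 62 features with a higher response in the root and 9 with a lower, and ABA synthesis and breakdown had 0 of 13 and 5. The MYB list does not hold GmMYB29B2 protein, whose response at 4 h was higher in the root by 5.78. The test of MYB factors gave adjusted p = 0.00187, and adjusted p = 0.372 with an estimated correlation, with counts of 3 and 18 adjusted over the list alone. The test of ABA synthesis and breakdown gave adjusted p = 0.00551, and adjusted p = 0.401 with an estimated correlation, with counts of 0 and 5 adjusted over the list alone.

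Some list counts of the root at 20 min were not given above. ABA signalling had 6 of 44 features higher and 1 lower, and 4 of the rises were of Protein phosphatase 2C. The list of ABA signalling had 9 and 1 adjusted over the list alone, with adjusted p = 0.000283, and adjusted p = 0.148 with an estimated correlation. Cell wall loosening had 16 of 140 higher and 2 lower, with 5 features each of Xyloglucan endotransglucosylase-hydrolase XTH9 and XTH3 higher. Its median change was -0.10, its mean 0.10 and its test leaned higher. The list of cell wall loosening had 20 and 3 adjusted over the list alone, with adjusted p = 0.364, and adjusted p = 0.778 with an estimated correlation.

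A hypothesis was that genes named Avr9/Cf-9 rapidly elicited may return towards their 0 min level in the leaf within 4 h. Of 104 such features 54 rose in the leaf at 40 min, and 26 of these were lower at 4 h than at 40 min by limma's test of that contrast, with 2 higher. Over all features 848 of the 2562 that rose at 40 min were lower at 4 h, and 405 higher. Over all 104 features, without choosing by a rise at 40 min, 27 were lower and 14 higher, against 7014 and 6391 of all features, and choosing features by their rise at 40 min favours lower values later. The 26 lie between the bounds set for and against the hypothesis, so the test left it open. In the root 80 of the 104 rose at 40 min and 5 of these were lower at 4 h, against 872 of 6756 over all features. The difference between the tissues in this respect was not tested. The median log2 change of the 104 features was 1.09 at 40 min and 0.75 at 4 h in the leaf, and 1.68 and 1.54 in the root.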
